A study of Mus musculus with 4 samples.

How the data were processed

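Single-cell RNA sequencing had been done on CD45+ cells, that is, cells carrying the pan-leukocyte surface protein CD45, sorted from MC38-EGFR tumours on day 14. MC38 is a mouse colon carcinoma line, and the EGFR in its name is the receptor that the antibody cetuximab binds. The 2 treatments were cetuximab and Cet×ICAM1-D1. Per the labels, live CD45+ cells of each tumour were sorted in equal numbers and pooled within a treatment, so a treatment is 1 pool of cells, and the tumours in it cannot be told apart.

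For each of the 4 samples the authors deposited a matrix of UMI counts, whole numbers of unique molecules per gene and barcode, not normalised. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10, with no settings. The labels name the 10x 3' kit, version 2. The deposited barcodes are 3 blocks of 9 bases, a form that the named kit does not give, and the step that made them is not given in the sources used here. The matrices list 33696 genes by symbol and identifier. Among these, 52 symbol entries share a symbol with another entry and were kept apart by identifier.

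The 4 samples are 2 sequencing runs of each of the 2 pools. Of the run 1 barcodes, 99.6% with cetuximab and 99.99% with Cet×ICAM1-D1 were also in run 2 of that treatment, against 1.45% to 1.98% between treatments. In each treatment 500 shared barcodes were drawn, and all 500 profiles in run 1 correlated best with their own barcode in run 2. The runs were therefore counted as 1 library per treatment. Run 2, the deeper run, gave the main values, run 1 is given for some of them, and UMIs were never added over runs. Run 1 was not clustered on its own. Its values cover the kept run 2 cells whose barcodes it holds, under the clusters and class names of run 2. Agreement between the runs is therefore no independent check.

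Before the data were examined, 2 replicates per treatment had been assumed, with edgeR quasi-likelihood tests of expression and shares, camera tests of gene lists and an exact permutation test of a cell ratio. With 1 library per treatment none of these has residual degrees of freedom among samples, and none was run. No p-value is given. Counts carry exact Poisson intervals, ratios of counts and of shares exact intervals conditional on their sum, and shares exact Clopper-Pearson intervals, all at 95% and all covering counting error only. A ratio of cell numbers within a treatment carries the exact Clopper-Pearson interval of the first class among both, turned into odds. A Wald interval on the log scale was used only to judge whether the ratio of these ratios between treatments moved.

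Barcodes with at least 500 UMIs, at least 250 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored per library with the Scrublet method in scanpy at an expected rate of 8%. Its automatic threshold marked 0% of barcodes in both libraries, so the planned fallback, removal of the top 8% of scores, was used. This removed 2486 barcodes (7.64%) with cetuximab and 2678 (7.92%) with Cet×ICAM1-D1, and 30059 and 31140 cells remained. Their median was 4429 UMIs with cetuximab and 5740.5 with Cet×ICAM1-D1.

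Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken without antigen receptor, ribosomal and mitochondrial genes, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1 with no integration. Clusters were named from fixed markers of 21 classes. A marker counted when at least 10% of a cluster's cells had it and its level was at least 2-fold that of the other cells, and a name needed at least 3 markers. The rules for clusters with markers of several classes were set after the clusters had been seen. These were a limit of 0.6 on the marker count of the next class relative to the best, a lead of 2 markers between T cell subsets, the name doublet-suspect above a median doublet score of 0.12, and no name for the cluster led by Egfr. Names are followed by "-like" at first use because they rest on markers alone. The share of every unnamed cluster is given in the report.

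UMI counts were summed over the cells of a class and scaled with TMM factors from edgeR. A ratio is the log2 of the level with Cet×ICAM1-D1 over that with cetuximab, both in CPM, the count scaled to a fixed library total, with a pseudocount of 0.5, so that a positive value means a higher level with Cet×ICAM1-D1. Classes with at least 50 cells per treatment were compared. Where a gene had 0 UMIs in a library the bound was computed against a floor of 3 UMIs. For 20 fixed lists of genes, the median ratio of the measured members was placed among the medians of 10000 random lists of the same size matched on expression in 30 bins, as a description of these libraries. A list is said to lie above or below its random lists when its median is outside their middle 95%.

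The genes named follow a rule fixed before the data were examined. It takes the 6 genes with the highest and the 6 with the lowest ratio in a population among those with a mean of at least 20 CPM, up to 4 members of each list that stands apart, Itgal, Itgb2 and Icam1 everywhere, and 5 effector or myeloid genes in named populations. The rule's p-value had to be replaced by the same direction in both runs. Antigen receptor, haemoglobin, mitochondrial, ribosomal and predicted genes stay out of its first part. Genes outside the rule, which are marker and background genes, were chosen after their values were seen, as were the lists and classes described in the text.

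Several choices followed a look at the data. They are the use of run 2, lowest UMI counts other than 500 and 1000, a lowest count matched for depth, the leaving out of the B cell, plasma cell, unset T cell, c27 and doublet-suspect clusters, the counting of cluster c10 as CD8 T cells, and limits of 0.1% and 2% on myeloid UMIs in lymphocytes. A filter on genes of free RNA was tried and dropped. Some genes, and a test of blood as the source of B lineage cells that rested on one of them, are not reported here. The alternatives planned before the data were examined were RLE scaling, filters on low counts, doublet removal, cell filters, clustering resolutions of 0.5 and 2, leaving out each sample, equal weight of classes for genes of the whole pool and thinning to equal depth for genes of a class. Equal weight of classes here means that each class had the same number of cells in both libraries. The lower of its cell numbers was drawn from each library, so the classes still differed in size. There were 1 main and 3 alternative clusterings and 399 list values in all.

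The computation was tested on simulated Poisson counts with known ratios, drawn independently for each gene. The intervals are exact for such counts, so their coverage checks the computation only. Variation between cells, tumours and pools, free RNA and genes of a list that change together were not simulated. For the whole pool, over 19229 genes, 95.6% of the intervals of unchanged genes held 0 and 96% of those of changed genes held the simulated ratio. In the same simulation 5% of 200 lists without a shift lay outside the middle 95%, and all 20 lists shifted by 0.3 lay above. For CD8 T cells, over 11768 genes, these values were 95.7%, 97.5%, 2.5% and 20. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.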

Results

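Leukocytes were sorted as live CD45+ cells from mouse MC38-EGFR tumours on day 14. The treatment was cetuximab, an antibody to EGFR, or Cet×ICAM1-D1, a bispecific antibody by the study's title whose name joins cetuximab to domain D1 of ICAM1. ICAM1 is the adhesion protein bound by the leukocyte integrin LFA-1, the pair of Itgal and Itgb2. The study asked how the 2 antibodies differ in their effect on single CD45+ cells. Each treatment was 1 pool of cells sequenced in 2 runs, so there was 1 library per treatment, no difference below has a replicate check, and intervals cover counting error only.

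With cetuximab, run 1 held 24768 barcodes and 77336997 UMIs and run 2 held 32703 barcodes and 226658388 UMIs. With Cet×ICAM1-D1, run 1 held 20318 barcodes and 39758087 UMIs and run 2 held 34700 barcodes and 275982591 UMIs. Values below are from run 2, in which 30059 cells were kept with cetuximab and 31140 with Cet×ICAM1-D1. Run 1 values take their cells and class names from run 2, so they are no independent check. The lowest UMI count of a deposited barcode in run 2 was 1489 with cetuximab and 952 with Cet×ICAM1-D1, so small cells with few UMIs could enter the shares of the second treatment more easily.

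The makeup of the sorted cells differed in several classes, among them the B lineage, macrophages and neutrophils. B cell-like cells, named like all classes here from fixed markers, made up 9.81% (95% interval 9.48 to 10.2, 2950 cells) of the cetuximab library and 0.244% (0.192 to 0.305, 76 cells) of the Cet×ICAM1-D1 library, a share ratio of 0.0249 that was 0.00731 in run 1. Macrophage-like cells, which express the complement genes C1qa, C1qb and C1qc, made up 13.3% (12.9 to 13.6) with cetuximab and 22.7% (22.3 to 23.2) with Cet×ICAM1-D1, a ratio of 1.72 (1.65 to 1.78). Neutrophil-like cells made up 3.31% (3.11 to 3.52) and 9.53% (9.20 to 9.86), a ratio of 2.88 (2.68 to 3.09). Regulatory T cell-like cells, which carry the transcription factor Foxp3, were at 2.41% (2.24 to 2.59) and 1.5% (1.36 to 1.64), a ratio of 0.620 (0.551 to 0.698). The shares of CD8 T cell-like cells, 3.96% and 3.78%, gave a ratio of 0.954 (0.879 to 1.03), and those of NK cell-like cells, 4.79% and 4.98%, a ratio of 1.04 (0.968 to 1.12), so among all kept cells of run 2 neither difference was beyond counting error, while the NK ratio in run 1 was 0.853.

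**Figure D1:**
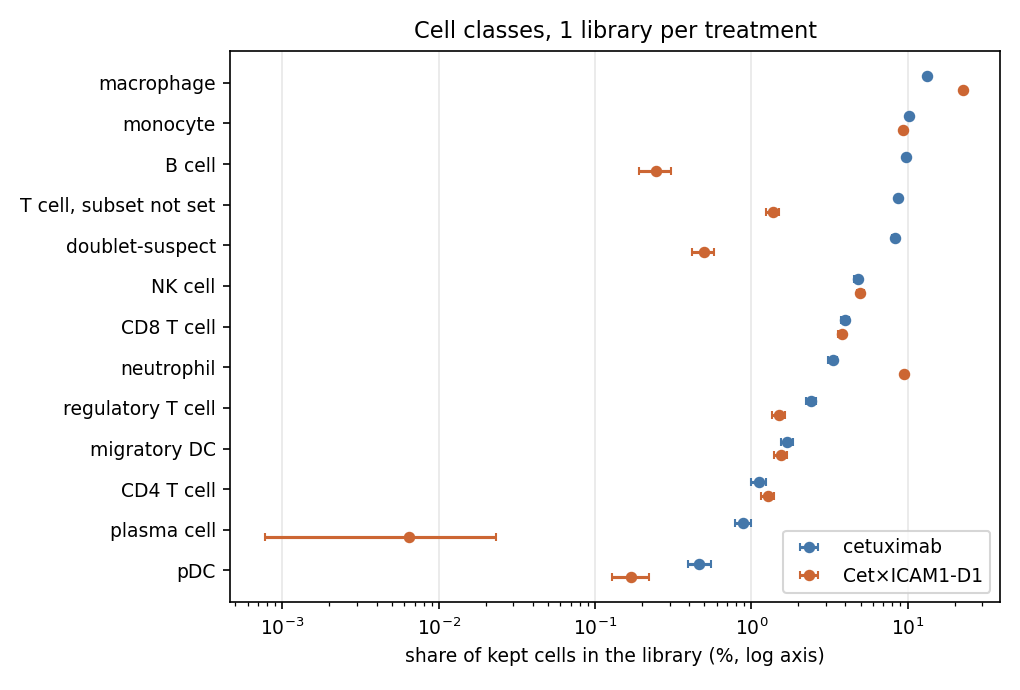
Share of each class among the kept cells of run 2 in percent on a log axis, with cetuximab and with Cet×ICAM1-D1, with exact 95% binomial intervals that cover counting error only. B cells made up 9.81% and 0.244% of cells and macrophages at 13.3% and 22.7%.

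Other lymphoid groups were also found nearly only with cetuximab. Plasma cell-like cells, the antibody secretors, numbered 266 with cetuximab and 2 with Cet×ICAM1-D1. Cluster c27 carried 7 B cell and 3 plasma cell markers but was left unnamed by the naming rules. It numbered 365 and 1, or 1.21% and 0.0032%. T cells whose subset could not be set, led by Tcf7 and Lef1, transcription factors of naive T cells, were at 8.69% and 1.37%, a ratio of 0.157 (0.142 to 0.174) that was 0.0957 in run 1. Clusters suspected to be doublets made up 8.29% and 0.495%. The largest, c10, with 1396 and 135 cells, had 6 CD8 and 6 CD4 T cell markers and was led by Ccl1, Penk and Ifng. Clusters c17 (261 and 1 cells), c23 (607 and 13) and c29 (229 and 5) each carried 7 B cell markers. Beside these, c17 had 6 CD8 T cell markers and c29 had 7 neutrophil markers. A cluster that comes mostly from 1 of 2 libraries may mark that library and not a cell type.

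Without the B cell, plasma cell, unset T cell, c27 and doublet-suspect clusters, 21373 and 30481 cells remained. The macrophage ratio was then 1.247, the neutrophil ratio 2.09, the CD8 T cell ratio 0.693, the regulatory T cell ratio 0.451, the NK cell ratio 0.756, the CD4 T cell ratio 0.831 and the monocyte ratio 0.663, where the smaller total with cetuximab lowers every ratio. Monocyte-like cells were at 10.3% and 9.36% of all kept cells, a ratio of 0.913 (0.868 to 0.961) that was 0.982 (0.933 to 1.03) at 1500 UMIs and 0.999 at matched lowest counts. CD4 T cell-like cells were at 1.11% and 1.27%, a ratio of 1.14 (0.987 to 1.33) that in run 1 was 0.497. Migratory dendritic cell-like cells were at 1.70% and 1.54%. Plasmacytoid dendritic cell-like cells, the main makers of type I interferon, numbered 140 and 53.

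The neutrophil share depended on the lowest UMI count allowed. Neutrophils had few UMIs, with a median of 2178 with cetuximab and 1641 with Cet×ICAM1-D1. The share ratio was 2.88 with all kept cells, 1.86 among cells with at least 1500 UMIs, 1.06 at 3000 and 0.618 at 5000. It was 1.60 when the lowest count was matched for the depth of the libraries, and 0.394 in run 1, where 8.86% of the Cet×ICAM1-D1 neutrophils but 82.8% of the cetuximab neutrophils had been seen. The macrophage ratio was 1.85 at 1500 UMIs and 1.49 at 5000, and that of B cells 0.0169 and 0.0465. At 5000 UMIs the ratio was 0.777 (0.691 to 0.873) for CD8 T cells and 0.384 (0.321 to 0.457) for regulatory T cells, both further from 1 than with all kept cells.

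**Figure D2:**
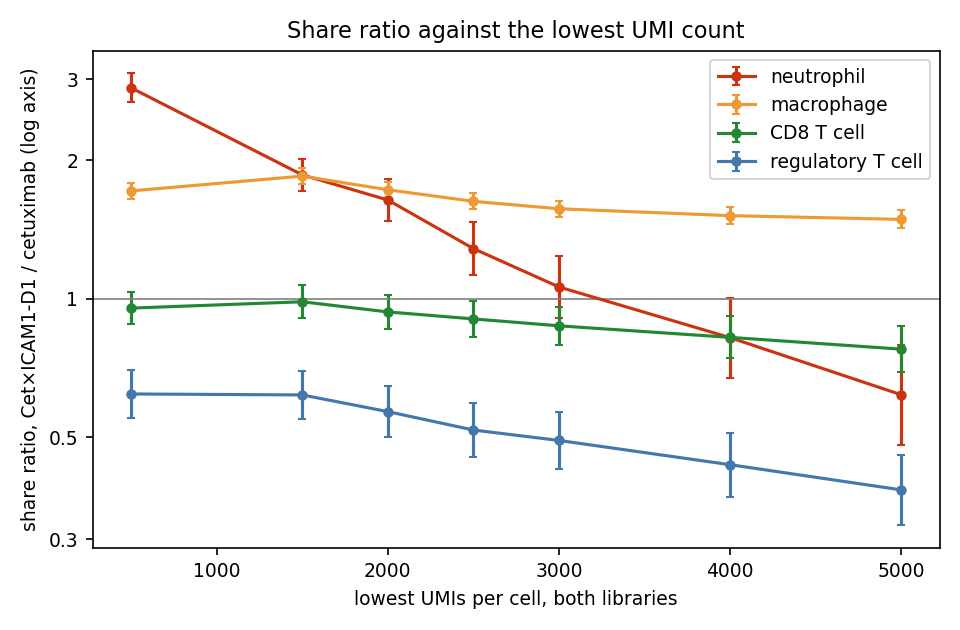
Ratio of class shares, Cet×ICAM1-D1 over cetuximab, on a log axis against the lowest number of UMIs allowed per cell in both libraries, with 95% counting intervals. The neutrophil ratio went from 2.88 at 500 UMIs to 0.618 at 5000, while the macrophage ratio stayed between 1.49 and 1.85.

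Among macrophages, the clusters led by Pf4 and C1qc and by the cell division genes Birc5, Plk1 and Ccnb1 each had a share ratio of 1.84, and the cluster led by Lyve1 and Cd163, genes of tissue-resident macrophages, one of 1.23. Among monocytes, the cluster led by Ly6c2 had a ratio of 1.04, that led by Ace and Treml4, genes of the non-classical monocyte, one of 0.648, and that led by interferon-induced Ifit genes one of 1.23. Several clusters stayed unnamed. Cluster c0, led by Clec5a, a myeloid receptor gene, was at 9.10% with cetuximab and 13.9% with Cet×ICAM1-D1, and c2, led by the dendritic cell genes Cd209a and Xcr1, at 2.58% and 2.42%. Cluster c8, led by Ereg, an EGFR ligand, and Il6, was at 4.40% and 5.56%, and c9, led by the heat shock genes Hspb1 and Hspa1a, at 8.13% and 10.4%. Without the doubted lymphoid clusters the ratios of c8 and c9, 1.26 and 1.28, were 0.917 and 0.932, the opposite direction, as were those of the Lyve1 macrophages (0.893), the Ly6c2 monocytes (0.758) and the Ifit monocytes (0.890). Cluster c7, of few UMIs, was at 1.53% and 3.15%, a ratio of 2.06 that was 0.410 in run 1. Cluster c12, led by mast cell proteases such as Mcpt1, was at 0.413% and 0.809%, a ratio of 1.96 (1.58 to 2.45), but it carried 8 NK cell markers beside 4 of mast cells, and at a resolution of 2 a mast cell cluster held 13 and 32 cells only, so the ratio is not that of mast cells alone. Cluster c13, led by Egfr but with 5 fibroblast markers, was at 3.02% and 5.38%, and c25, led by Ctsk, at 0.665% and 1.31%.

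The balance of CD8 to regulatory T cells, which sets killer against suppressor lymphocytes, was 1.64 (1.5 to 1.80) with cetuximab, from 1191 and 725 cells, and 2.53 (2.27 to 2.82) with Cet×ICAM1-D1, from 1177 and 466 cells. The ratio of the ratios was 1.54 and in run 1 it was 1.78. With clustering at a resolution of 0.5 it was 0.780, the opposite direction, and 2595 cells with cetuximab and 1303 with Cet×ICAM1-D1 then had the CD8 name, among them 1325 and 120 of the doublet-suspect cluster c10. With c10 counted as CD8 T cells at the main resolution it was 0.789, so the direction depends on setting c10 aside.

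Over the whole CD45+ pool, which mixes composition with expression, the genes with the lowest ratios were those of the B lineage. Mzb1, a chaperone of antibody secretion, had a log2 ratio of -6.61 (-6.81 to -6.41), Jchain, which joins antibody units, -6.13 (-6.23 to -6.04), and Cd79a, part of the B cell receptor, -6.04 (-6.18 to -5.90). The highest ratios included Egfr at 1.16 (1.14 to 1.18), from 124 to 277 CPM, and Fcrls, a myeloid Fc receptor-like gene, at 1.06 (1.01 to 1.11). Of the genes of LFA-1 and its ligand, Itgal was at -0.32 (-0.35 to -0.30), Itgb2 at 0.17 (0.16 to 0.19) and Icam1 at 0.24 (0.20 to 0.28).

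All 13 genes of naive and memory T cells were lower in the whole pool, with a median log2 ratio of -0.94, including Tcf7 at -2.43 and Lef1 at -2.30. Of the 18 type I interferon genes 16 were lower, with a median of -0.20, among them Ifit3, which blocks viral RNA, at -0.43. The LFA-1 and adhesion list had 8 of 25 members higher and a median of -0.10, at the 0.740 percentile of its random lists, but it lay inside them in run 1, at -0.096, and with at least 10 CPM, at -0.068. Of 23 proliferation genes 19 were higher, with a median of 0.23 that lay above all random lists, and Mki67, a mark of dividing cells, was at 0.23 (0.21 to 0.25). The suppressive and tissue-repair macrophage list had 12 of 19 members higher and a median of 0.15. That median was -0.01 when each class had the same number of cells in both libraries.

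The other 15 lists in the whole pool were as follows. Medians lay below the random lists for MHC class I presentation (-0.12), MHC class II presentation (-0.09), cytotoxic effectors (-0.17), T cell exhaustion (-0.35), T cell activation (-0.40) and regulatory T cell effectors (-0.51). They lay above for Fc receptors and phagocytosis (0.13), chemokines (0.15) and mitochondrial transcripts (0.19). In run 1 the median was -0.016 for chemokines and 0.042 for MHC class II presentation, both of the opposite sign. They lay within for the interferon gamma response (0.05), inflammatory macrophage genes (0.04), hypoxia and glycolysis (0.05), neutrophil suppressor genes (0.12), checkpoint ligands (0.10) and dissociation stress (0.01), and the neutrophil suppressor median was -0.36 in run 1. Gzmb, which encodes the killing protease granzyme B, was at -0.20 and the checkpoint receptor gene Pdcd1 at -0.31. Both were higher, at 0.15 and 0.27, when each class had the same number of cells in both libraries. Ifng, the gene of interferon gamma, was at -0.96 (-0.99 to -0.92) and Prf1, which encodes the pore protein perforin, at 0.22 (0.19 to 0.24).

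In CD8 T cells the cytotoxic and exhaustion genes were higher with Cet×ICAM1-D1. T cell lineage genes were higher too, from 0.18 for Cd8b1 to 0.58 for Trac, so the rise was not particular to these lists. Of 17 cytotoxic effector genes 13 were higher, with a median log2 ratio of 0.30 at the 99.97 percentile that was 0.14 and within the random lists without doublet removal, among them Prf1 at 0.69 (0.63 to 0.75), the chemokine Ccl5 at 0.67 (0.62 to 0.72) and the death ligand Fasl at 0.66 (0.51 to 0.81). Of 15 exhaustion genes 12 were higher, with a median of 0.39, among them Pdcd1 at 0.71 (0.61 to 0.80) and Lag3, an inhibitory receptor, at 0.53 (0.45 to 0.62). The dissociation stress list was at -0.11, below its random lists. Gzmb was at 0.22 (0.19 to 0.25), Ifng at -0.24 (-0.28 to -0.20) and Mki67 at 0.03 (-0.03 to 0.08). Of 13 naive and memory genes 9 were lower, with a median of -0.26, including Tcf7 at -1.27 (-1.55 to -1.01). That list lay below its random lists in 18 of 20 populations, with medians of -0.75 in macrophages and -0.55 in monocytes, so its fall was not particular to T cells.

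The single genes with the highest ratios in CD8 T cells were Penk, which encodes a precursor of enkephalin peptides, at 2.42 (2.1 to 2.76), and the chemokines Ccl1 at 1.35 (1.26 to 1.44) and Xcl1, which attracts cross-presenting dendritic cells, at 1.27 (1.20 to 1.34). With cluster c10 counted as CD8 T cells Penk was at 0.21, Ccl1 at 1.63 and Ifng at 0.64, the opposite direction, and the medians were 1.13 for cytotoxic and 0.81 for exhaustion genes. The lowest were genes of myeloid cells, among them the chemokines Ccl7 at -1.93 (-2.1 to -1.76) and Cxcl9 at -1.84 (-2.0 to -1.68), and 14 of 16 inflammatory macrophage genes were lower, with a median of -1.06. C1qa, a macrophage gene, was at 318 CPM in CD8 T cells with cetuximab and 102 with Cet×ICAM1-D1, and the antibody gene Igkc at 140 and 2.61 CPM. The T cell genes Cd3e, Cd3d, Trac, Cd8a and Cd8b1 were themselves higher, at 0.39, 0.52, 0.58, 0.45 and 0.18. Among CD8 T cells with under 0.1% myeloid UMIs, 351 and 365 cells, the medians were 0.25 for cytotoxic and 0.21 for exhaustion genes. Beside them Cd3e was at 0.31, Cd3d at 0.35, Trac at 0.46, Cd8a at 0.23 and Cd8b1 at -0.10.

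In regulatory T cells all 13 effector genes were higher with Cet×ICAM1-D1, with a median log2 ratio of 0.87 above all random lists and 0.82 in run 1. Il1rl1, the receptor of the alarm cytokine IL-33, was at 1.14 (0.90 to 1.37), the suppressive cytokine gene Il10 at 1.07 (0.93 to 1.21), Il2ra, part of the high-affinity interleukin receptor that marks these cells, at 1.06 (0.99 to 1.13) and the costimulatory receptor gene Tnfrsf18 at 0.99 (0.90 to 1.08). Of these 13 genes 7 were also markers that named the class. Tcf7 was at -3.62 (-4.56 to -2.91), Penk at 1.40 (1.253 to 1.55) and Icam1 at 0.74 (0.50 to 0.96). Of 20 chemokine genes 17 were lower, with a median of -0.60, led by Ccl8 at -2.33 (-2.73 to -1.96). The dissociation stress list was at -0.22, below its random lists. Cd3d and Trac were higher at 0.54 and 0.72, and C1qa was at 553 CPM with cetuximab and 259 with Cet×ICAM1-D1. In the 126 and 71 regulatory T cells with under 0.1% myeloid UMIs the effector median was 1.28, and that of chemokines was 0.82, the opposite direction.

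In NK cells, whose cluster was led by granzyme genes such as Gzmd, 10 of 17 cytotoxic genes were higher, with a median log2 ratio of 0.23 that lay within the random lists, at the 94 percentile, but above them with at least 10 CPM, at 0.29, and with no filter, at 0.23. All 16 inflammatory macrophage genes measured were lower, with a median of -1.45. The granule protease Ctsg was at 1.55 (1.26 to 1.86) and the amino acid carrier Slc7a5, used by activated lymphocytes, at 0.97 (0.76 to 1.18), while Inhba, which encodes an activin subunit, was at -2.34 (-2.47 to -2.22). Itgb2 was lower at -0.66 (-0.76 to -0.56) and Itgal at 0.14 (0.06 to 0.22). The medians were 0.38 for mitochondrial transcripts, above the random lists, and -0.26 for dissociation stress, below them. C1qa was at 247 and 151 CPM, the NK receptor genes Ncr1 and Klrb1c were at 0.33 and 0.19, and in the 253 and 301 cells low in myeloid UMIs the cytotoxic median was 0.03 and Itgal was at -0.053.

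CD4 T cells came from a cluster led by cytokine genes such as Il5, Il13 and Il17a, with 335 cells under cetuximab and 397 under Cet×ICAM1-D1. All 22 proliferation genes measured were higher with Cet×ICAM1-D1, with a median log2 ratio of 0.89, among them Rrm2, which makes DNA building blocks, at 1.96 (1.14 to 2.95) and the cyclin Ccnb2 at 1.85 (0.95 to 2.94). Of 16 cytotoxic genes 12 were higher, with a median of 0.74, including Prf1 at 1.70 (0.91 to 2.63) and Ifng at 1.44 (1.252 to 1.63). The T cell growth factor gene Il2 was at -6.60 (-9.10 to -5.26), from 321 to 3 UMIs, the type 2 cytokine Il4 at -2.67 (-3.30 to -2.12) and the inhibitory receptor Btla at -2.73 (-3.54 to -2.06). Sostdc1, a secreted inhibitor of BMP signalling, had 95 UMIs and 0, at least 33.4-fold lower. Of 13 naive and memory genes 11 were lower, with a median of -0.71. Genes of other cells fell, with all 12 MHC class II genes lower at a median of -1.15 and from 222 to 150 CPM for C1qa and 173 to 2.47 for Igkc, and the medians were 0.21 for dissociation stress and -0.10 for mitochondrial transcripts, both outside their random lists and of the opposite sign in run 1. Cd3d and Cd4 were at 0.41 and 0.44, Trac at 0.17 and Cd3e at 0.099 (-0.086 to 0.285). Of the Cet×ICAM1-D1 cells 29.98% had been seen in run 1 against 88.4% with cetuximab.

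In macrophages inflammatory genes had a median log2 ratio of -0.06, with 5 of 17 higher, and suppressive and tissue-repair genes one of 0.02, with 10 of 19 higher, both within their random lists. The inflammatory list lay below its random lists in run 1, at -0.20, and without doublet removal, at -0.15. All 18 type I interferon genes were lower, with a median of -0.27, including Ifit3 at -0.55 (-0.70 to -0.40) and Rsad2, an antiviral enzyme, at -0.51 (-0.59 to -0.43). That list also lay below its random lists in NK cells, at -1.03, CD4 T cells, at -0.58, and CD8 T cells, at -0.47. Lists that follow RNA quality also differed in macrophages, with medians of 0.30 for mitochondrial transcripts, above all random lists, and -0.11 for dissociation stress, below them. Lyve1, a receptor of tissue-resident macrophages, was at 1.02 (0.90 to 1.15) and Htra3, a secreted protease, at 0.98 (0.85 to 1.10). The chitinase-like Chil3 was at -1.54 (-1.59 to -1.48) and the eosinophil chemokine Ccl24 at -1.43 (-1.52 to -1.34).

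Among the genes fixed for macrophages, Arg1, which depletes arginine, was at -0.06 (-0.06 to -0.05), Nos2, which makes nitric oxide, at -0.37 (-0.40 to -0.34) and Cd274, which encodes PD-L1, at -0.32 (-0.35 to -0.28). Cxcl9, a chemokine that draws T cells, was at -0.06 (-0.08 to -0.05) and H2-Ab1, an MHC class II gene, at -0.13 (-0.14 to -0.11), and in run 1 both had the opposite sign, at 0.13 and 0.06. T cell exhaustion genes, 13 of 15 of them lower, had a median of -1.42 in macrophages, and Igkc was at 122 CPM with cetuximab and 1.35 with Cet×ICAM1-D1.

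In monocytes the interferon genes were higher with Cet×ICAM1-D1, unlike in macrophages, although the difference between the classes was not tested. Of 18 interferon gamma genes 17 were higher, with a median log2 ratio of 0.24, among them Cxcl9 at 0.50 (0.47 to 0.53) and Irgm2, a guanosine triphosphatase of cell defence, at 0.46 (0.32 to 0.60). Of 18 type I interferon genes 15 were higher, with a median of 0.16, which was 0.01 without doublet removal. The class differed in makeup, as the Ifit cluster was 12.5% of monocytes with cetuximab and 16.8% with Cet×ICAM1-D1 and the Ace and Treml4 cluster 38.7% and 27.4%. The suppressive and tissue-repair list had 13 of 18 members higher, with a median of 0.22, including Il10 at 1.05 (0.81 to 1.29). Apoe, a lipid carrier of macrophages, was at 0.72 (0.68 to 0.76), Ccl5 at 0.69 (0.64 to 0.74), Arg1 at 0.32 (0.30 to 0.34), H2-Ab1 at 0.24 (0.22 to 0.25), Nos2 at 0.13 (0.09 to 0.17) and Cd274 at 0.12 (0.08 to 0.16). The T cell ligand gene Cd40lg had 17 UMIs with cetuximab and 0 with Cet×ICAM1-D1, at least 5.50-fold lower. C1qa was at 343 CPM with cetuximab and 501 with Cet×ICAM1-D1 and the T cell gene Cd3e at 7.77 and 2.88, and the medians were 0.15 for mitochondrial transcripts and -0.11 for dissociation stress, both outside their random lists.

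In neutrophils all 16 suppressor genes were higher with Cet×ICAM1-D1, with a median log2 ratio of 0.68. They included Wfdc17 at 1.12 (1.05 to 1.19) and the calprotectin genes S100a9 at 1.08 (1.06 to 1.11) and S100a8 at 1.03 (1.0 to 1.05). In run 1 the median was 0.24 over the genes passing its own low-count filter and lay within its random lists, and 4 of the 16 genes were also markers that named the class. The genes with the highest ratios included the granule genes Ngp at 7.03 (5.49 to 10.40), from 2 to 532 UMIs, Camp at 3.86 (3.03 to 5.01), Lcn2 at 1.73 (1.60 to 1.87) and Ltf at 1.81 (1.30 to 2.39), beside the growth factor gene Csf3 at 2.11 (1.66 to 2.61). Of 23 proliferation genes 21 were higher, with a median of 0.82, and all 12 MHC class II genes were lower, with a median of -0.96, and in run 1 these medians were 0.43 and -0.25. That of mitochondrial transcripts was -0.18 and in run 1 0.50. Il6 was at -1.71 (-1.99 to -1.45), Icam1 at 0.61 (0.46 to 0.77) and Itgb2 at -0.31 (-0.42 to -0.19), which was 0.26 in run 1. Across genes, which are not independent replicates, the ratios of the runs correlated at 0.425 in neutrophils against 0.856 in macrophages, and the cells compared differ with the lowest UMI count as given above.

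**Figure D3:**
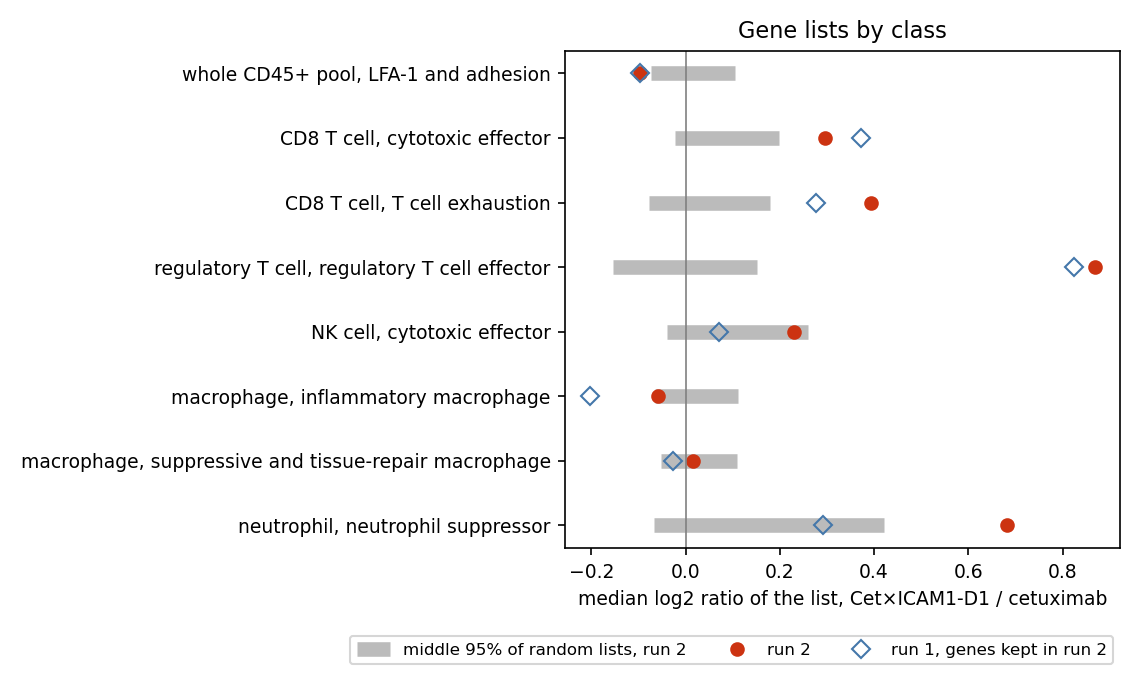
Median log2 ratio, Cet×ICAM1-D1 over cetuximab, of 8 gene lists, each in the population named before it, from run 2 (circles) and from run 1 over the genes kept in run 2 (diamonds), with grey bars for the middle 95% of 10000 expression-matched random lists in run 2. The regulatory T cell effector list lay at 0.87 in run 2 and 0.82 in run 1, and the neutrophil suppressor list at 0.68 and 0.29. Run 1 values are from the same cells under the class names of run 2.

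Over all populations, 399 list medians were computed, of which 65 lay above and 166 below their random lists. By chance 19.95 in all would lie outside if the members of a list varied independently of each other. Members of a list can change together and the whole pool contains every class, so the excess over that number is not a test. In the B cells and plasmacytoid dendritic cells, with 76 and 53 cells under Cet×ICAM1-D1, no single gene is named.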

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

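The comparison of barcodes between runs was chosen after the result was seen. The samples numbered as a second replicate of each treatment stood out because run 1 turned out to hold the same cells as run 2. Of the run 1 barcodes, 99.645% with cetuximab and 99.985% with Cet×ICAM1-D1 were found in run 2 of the same treatment. The median correlation of a cell's profile in run 1 with its own barcode in run 2 was 0.767 with cetuximab and 0.685 with Cet×ICAM1-D1, against 0.415 and 0.454 with other barcodes. Per shared barcode, run 2 held a median of 2.66 times as many UMIs as run 1 with cetuximab and 5.99 times with Cet×ICAM1-D1. No biological explanation was tested, and the runs were treated as repeat sequencing of 1 library per treatment.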

How the results depend on the processing

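No test gave these values, so a difference is said to turn when its sign changes and to move when it leaves the 95% counting interval, and a list to change when it crosses the middle 95% of its random lists. The settings from run 1, of at least 1500 UMIs, of a matched lowest count, without the doubted lymphoid clusters of lymphocytes low in myeloid UMIs and of c10 counted as CD8 T cells, and for lists equal weight of classes and, for lists and genes of the whole pool, thinning, were chosen after the data were seen. Over all settings, of 174 class share values 59 moved and 4 turned, of 238 cluster share values 54 moved and 5 turned, of 397 list values 22 were weaker, 5 stronger and 3 turned, and of 2915 gene values 580 moved and 25 turned. These totals include the settings that leave out the run 1 sample of a treatment. Those settings equal the main values and could not move, so the totals overstate stability. RLE scaling shifted all genes by at most 0.011 in any class. Filters on low counts leave a gene's own ratio as it is, so they were applied to lists only. DESeq2 and camera variants were not run, since without replicates they give no test. No paired analysis was possible because the samples that share a number are runs of 1 library per treatment and no test was fitted. Cluster shares have no value without doublet removal, as the clusters are then others. Values of regulatory and CD4 T cells, and so the CD8 to regulatory T cell ratio, have none either, as no cluster then had these names. The cluster led by Foxp3 had 6 regulatory and 5 CD4 T cell markers, short of the lead required between T cell subsets. The cause was not tested for any of the values that follow, except where the setting itself selects the cells.

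The ratio of CD8 to regulatory T cells, 1.54, was 0.780 at a Leiden resolution of 0.5, 0.789 with cluster c10 counted as CD8 T cell and 1.78 in run 1, with a range of 1.54 to 1.70 when a sample was left out. In run 1 the ratio was 0.00731 for the share of B cells, 1.99 for the share of macrophages, 0.394 for the share of neutrophils (cluster c15), 0.509 for the share of regulatory T cells and 0.410 for the share of cluster c7. With at least 1500 UMIs they were 0.0169 for B cells, 1.85 for macrophages and 1.86 for neutrophils, and with matched lowest counts 0.0145, 1.89 and 1.60. Without the doubted clusters they were 0.693 for the share of CD8 T cells, 1.247 for macrophages, 2.09 for neutrophils and 0.451 for regulatory T cells, which the smaller denominator gives by construction. TMM on the class counts gave 0.841, 1.51, 2.53 and 0.547 for the same classes. With cluster c10 counted as CD8 T cell the ratio was 0.490 for the share of CD8 T cells and Ifng in CD8 T cells was at 0.64. Without doublet removal the ratio was 1.19 for CD8 T cells, 1.97 for macrophages and 1.03 for the share of monocytes. Among named immune classes only, the macrophage ratio was 1.84. At a Leiden resolution of 0.5 it was 0.485 for CD8 T cells and 1.22 for monocytes, and at 2 it was 3.18 for neutrophils.

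Each sample was left out in turn. Leaving out the run 1 sample of a treatment leaves the main values as they are. Leaving out its run 2 sample takes that treatment from run 1. Over these settings the ratio ranged from 0.00449 to 0.0405 for the share of B cells, 0.804 to 1.08 for the share of CD8 T cells, 1.43 to 2.39 for the share of macrophages, 0.437 to 2.88 for the share of neutrophils (cluster c15), 0.498 to 0.634 for the share of regulatory T cells, 0.587 to 1.12 for the share of cluster c19 and 0.458 to 2.06 for the share of cluster c7. The list medians ranged from -0.097 to -0.074 for LFA-1 and adhesion in the whole pool, -0.15 to -0.058 for inflammatory genes in macrophages and 0.22 to 0.68 for suppressor genes in neutrophils. In neutrophils Ciita ranged from -1.29 to 0.24 and Itgb2 from -0.33 to 0.27, in macrophages Cxcl9 ranged from -0.074 to 0.13, and Oas1a ranged from -0.62 to 0.12 in monocytes and from -0.61 to 0.054 in the whole pool.

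In run 1 the LFA-1 and adhesion list was at -0.096 in the whole pool, inside its random lists, inflammatory genes in macrophages at -0.20, below theirs, and suppressor genes in neutrophils at 0.24, inside theirs. In run 1 Ciita and Itgb2 were at 0.17 and 0.26 in neutrophils, and Cxcl9 and H2-Ab1 at 0.13 and 0.061 in macrophages, all turned. With at least 10 CPM in both libraries the LFA-1 and adhesion list was at -0.068, inside its random lists, and cytotoxic genes in NK cells at 0.29, above theirs, as they were at 0.23 with no filter. Without doublet removal cytotoxic genes in CD8 T cells were at 0.14, within their random lists, inflammatory genes in macrophages at -0.15, below theirs, type I interferon genes in monocytes at 0.014, Ccnb2 in migratory dendritic cells at 0.18 and Itgal in CD8 T cells at -0.083. With the same number of cells of each class in both libraries, Gzmb was at 0.15 and Pdcd1 at 0.27 in the whole pool. The median for suppressive and tissue-repair macrophage in whole CD45+ pool counts was then -0.0090.

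Among lymphocytes with under 0.1% myeloid UMIs, a setting that removes myeloid RNA by construction, the values that turned were, in regulatory T cells, Ccl12 at 0.56, Ccl7 at 0.82, Ccl8 at 1.52, Ch25h at 0.82, the chemokine list at 0.82 and Ly6c1 in regulatory T cells at -2.12, Ccl7 at 0.030 and Gatm at 0.31 in CD8 T cells, Ccl17 at 0.17 in CD4 T cells, and Itgal at -0.053, Ly6i at 0.053 and Rsad2 at 0.012 in NK cells. Few cells limit these values, with 71 regulatory T cells under Cet×ICAM1-D1.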

Other observations

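The tests in this part, the populations described and the genes of other cell types were all chosen after the results were seen. Migratory dendritic cells, which carry antigen to lymph nodes, had 9 of 13 checkpoint ligand genes higher with Cet×ICAM1-D1, with a median log2 ratio of 0.59 above all random lists. Tnfsf4, the ligand of OX40, was at 1.26 (0.95 to 1.57), Cd70, the ligand of CD27, at 0.95 (0.58 to 1.34) and Pdcd1lg2, a ligand of PD-1, at 0.84 (0.67 to 1.02), whereas Lgals9, which encodes a galectin, was at -1.28 (-1.89 to -0.74). Il12b, part of a cytokine that activates T and NK cells, was at 1.47 (1.36 to 1.58). The LFA-1 and adhesion list had 9 of 24 members higher and a median of -0.27, with Itgal at -1.22 (-1.52 to -0.94) and Itgb2 at -1.03 (-1.25 to -0.81). All 23 proliferation genes were lower, with a median of -0.63 that was -0.06 without doublet removal. Apol7c, a gene of dendritic cells, was at -2.16 (-2.41 to -1.94), while genes of other cells fell as well, from 253 to 142 CPM for C1qa, 102 to 49.5 for Cd3e and 333 to 168 for Nkg7.

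Cluster c25 was led by Ctsk, Mmp9, Acp5 and Oscar, genes of bone-resorbing osteoclasts, and held 200 cells with cetuximab and 409 with Cet×ICAM1-D1. Of its 23 proliferation genes 22 were higher, with a median of 1.004, among them Mki67 at 2.06 (1.83 to 2.31). All 17 type I interferon genes measured there were lower, with a median of -0.77, led by Rsad2 at -3.08 (-3.58 to -2.62). The medians there were also -1.03 for naive and memory T cell and -0.60 for MHC class II genes, below their random lists, and 0.19 for mitochondrial transcripts, above, and Igkc fell from 67.4 to 2.21 CPM. Cluster c13 was led by Egfr, at 2015 CPM with cetuximab and 2929 with Cet×ICAM1-D1, and had little of the CD45 gene Ptprc, at 68.9 and 43.5 CPM, although CD45+ cells had been sorted. It also carried 5 fibroblast markers and would have had that name without the rule on Egfr. At a resolution of 2, a cluster of 589 and 984 cells was led by the collagen genes Col1a2 and Col3a1. Another, of 262 and 487 cells, had Egfr among its leading genes. The ratios of c13 may therefore not be those of 1 cell type. All 18 of its type I interferon genes and all 12 MHC class II genes were lower, with medians of -0.56 and -0.88, and 17 of 18 interferon gamma genes were lower, with a median of -0.47. Lists of other cells fell too, with -0.31 for inflammatory macrophage and -0.77 for naive and memory T cell genes, and mitochondrial transcripts were at 0.23 and dissociation stress at -0.23. Saa3, an acute phase gene, was at 1.505 (1.31 to 1.71) and the chemokine Cxcl14 at -3.03 (-3.32 to -2.76) in that cluster.

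B cells, plasma cells, T cells of unset subset and cluster c27 were found nearly only with cetuximab. Loss of small cells at the lowest UMI count is argued against for these groups. That count was higher with cetuximab, 1489 against 952 with Cet×ICAM1-D1, so such loss would fall more on the cetuximab library. With matched lowest counts the share ratio was 0.0145 for B cells and 0.130 for T cells of unset subset, further from 1 than with all kept cells. Among cells with at least 5000 UMIs the share ratio was 0.0465 (0.0123 to 0.125) for B cells, 0.00891 for plasma cells, 0.0044 for c27 and 0.346 (0.247 to 0.479) for T cells of unset subset. Blood as the source is not weighed here. Lymphoid tissue taken along with the cetuximab tumours may account for the pattern and stays open, because the naive and memory T cell list also lay below its random lists in 4 of 5 myeloid classes, which free RNA of such tissue could give but which does not show where the cells came from. The antibody treatment stays open as well, and with 1 independent library per treatment it cannot be told apart from a difference between the pools.

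Neutrophils made up a larger share with Cet×ICAM1-D1. A candidate explanation is the different lowest UMI counts of the deposited barcodes, which would let more of these small cells into that library. It accounts for part of the pattern, since the share ratio was 1.60 at matched lowest counts against 2.88 without matching, and it was 0.618 among cells with at least 5000 UMIs. What remains at the matched count may come from the antibody treatment, for which 1 independent library per treatment gives no test.

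Genes of myeloid cells were lower in CD8 T, NK and regulatory T cells with Cet×ICAM1-D1. Free RNA shared by all cells is argued against as the whole cause, since the 9 macrophage markers summed, at -1.34, -0.70 and -1.09 in these classes, were at 0.45 (0.35 to 0.55) in T cells of unset subset, 0.88 in B cells, 1.04 in plasmacytoid dendritic cells, -0.0036 in c13 and -0.0053 in neutrophils, though lower in CD4 T cells at -0.28, c12 at -0.56 and migratory dendritic cells at -0.80, with a median of -0.0045 over these 8. Per cell the difference was smaller. The median percent of myeloid UMIs was 0.176 with cetuximab and 0.152 with Cet×ICAM1-D1 in CD8 T cells. It was 0.202 and 0.188 in NK cells and 0.262 and 0.236 in regulatory T cells. That percent covers 25 macrophage, monocyte and neutrophil markers, so it is not directly comparable with the sums. Cells with over 2% myeloid UMIs were few, 5 and 1 CD8 T cells, 15 and 6 NK cells and 14 and 1 regulatory T cells, and the lowest ratio, 2.69 (0.988 to 8.48) in NK cells, does not decide for joined droplets. Lymphocytes joined to a myeloid cell and the antibody treatment, which was not tested, stay open.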
